A study of Caenorhabditis elegans with 2 samples.

How the data were processed

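The 2 samples were whole L4 larvae of strain OP203, which expresses eGFP-tagged NHR-76, each immunoprecipitated and sequenced as a separate biological replicate per the labels. Both fell in 1 group, and the replicate numbers were taken from the labels. The deposited files were 8 lists of regions in the 10-column narrowPeak layout, 4 on the ce11 build and 4 on ce10. Per the texts deposited with the samples, each replicate list held the peaks and background regions found on the alignment of that replicate with a further file, the pooled list was made from both alignments with that same file, and the called list was derived from the pooled and both replicate lists by the irreproducible discovery rate (IDR), which keeps peaks whose ranks recur in both replicates. The peak caller, the aligner and the thresholds are not given in the sources used here. A possible control is named in the labels, and whether it entered the lists is not given in the sources used here. Size selection was recorded per the labels, while the extraction protocol was not given.

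The main value per region was the deposited signal value, a score whose scale is not stated, and it was used only to rank regions within a list. The deposited -log10 of the q-value was 2.87 for every called ce11 peak and therefore ranked nothing. The summit offset deposited for each region gave the summit position. Since no counts were used, the depth per sample is unknown, and no interval that needs depth was made. Of the 319 called ce11 peaks, 111 had the start and end of a pooled region and 315 had a pooled summit within 200 bp, so the called list was not a subset of the pooled list. Uncalled regions were therefore defined as pooled regions with no called summit within 200 bp. This left 12728 of 13052 pooled regions. The depositors named the pooled list, too, as peaks and background, so uncalled regions may be background signal rather than weaker peaks. Ranks were compared between the replicate lists, whose lengths differ, by taking equal numbers of the strongest regions. Signal values were not compared between lists, and no position was converted between builds. The ce10 lists were used only for counts and for replicate overlap.

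Genes were taken from Ensembl release 115 on WBcel235, which is the ce11 sequence, without piRNA genes. Sequence came from the NCBI copy of the same assembly, and no region of the ce11 lists ran past a chromosome's end in it. A summit was assigned to a promoter (1000 bp upstream to 200 bp downstream of the 5′ end of a protein-coding gene), otherwise to an exon, an intron or intergenic sequence. A gene counted as bound when a called summit lay in its promoter window, both genes of a divergent pair included. Classes, chromosomes, gene lists, motifs and small RNA genes were compared with two-sided Fisher's exact tests. Odds ratios had 0.5 added to each cell, with 95% intervals, and p-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05. The 20 gene lists and 19 motifs were fixed before the data were examined. For motifs, 200 bp windows at called summits were set against 5 uncalled regions per peak of the same promoter class and GC decile. Replicate overlap was tested with 1000 random re-rankings (100 for the settings that count overlapping regions), and the nhr-76 locus with 10000 random positions on its chromosome. Peaks of 1 experiment are not independent replicates, and the p-values cover only the assignment of regions.

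Genes to be named were chosen by a rule fixed before the data were examined. They were the genes at the 25 strongest called peaks, the 4 members of each list with the strongest called peaks, and nhr-76, atgl-1 and npr-22. Since 25 of the 31 strongest called peaks were mitochondrial, the genes at the 25 strongest nuclear peaks were added after seeing the data. Of the mitochondrial genes only COX3, at the strongest peak, is named.

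The alternatives fixed beforehand were promoter windows of 500 and 2000 bp, the 159 strongest called peaks, the 319 strongest regions of 1 replicate in place of the called peaks, the 50 kb around nhr-76 left out, stronger uncalled regions only, all protein-coding genes as the background, only the nearest gene, 100 bp motif windows, an unmatched motif background, other definitions of a shared region, small RNA genes within 1000 bp, and locus windows of 20 and 100 kb. Where a replicate is said to be left out, the 319 strongest regions of the other replicate stood in for the called peaks, without IDR. The pooled list from both replicates stayed the source of the uncalled regions, so the replicate was not wholly removed. Leaving out mitochondrial peaks, alone or with X-linked ones, was added after seeing the data.

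The tests were checked on simulated data. In 20 draws of 319 regions from the 13022 nuclear pooled regions with promoter odds of 4, the median odds ratio was 4.06 and all 20 draws passed, and with odds of 1 none of 20 did. For gene lists, the background was the genes with a nuclear pooled region in the promoter window. A weight of 8 on regions at ribosomal protein promoters was called in 20 of 20 draws with a median odds ratio of 10.5, and 1 call arose among the unchanged lists in 40 draws. For motifs, AGGTCA written into 20% of windows was called in 10 of 10 draws, and in 0 of 10 without it. That share is far larger than the differences seen for the receptor elements, so this check does not show that smaller differences would be found. For replicate overlap, 50% sharing was planted among 4712 regions, and the share counted, 50.2%, was fixed by how the lists were built. The permutation test passed in 20 of 20 of these draws, and in 0 of 20 draws without planted sharing. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.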

Results

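Binding of NHR-76 to the genome of Caenorhabditis elegans was measured by chromatin immunoprecipitation and sequencing (ChIP-seq), in which DNA bound by a protein is recovered with an antibody and sequenced. NHR-76 is a member of the nuclear hormone receptor family of transcription factors, and it has been linked to the control of the fat lipase gene atgl-1 in the intestine. The protein carried an enhanced green fluorescent protein (eGFP) tag, expressed from a transgene in strain OP203, and whole larvae of the last larval stage (L4), mixed in sex, were used. The design had 1 group with 2 biological replicates, so the comparisons were between the replicates and between the peaks called from both and the other regions of the same experiment. The values were lists of regions with a signal value per region, which the authors' processing gave and whose scale the sources used here do not state, so a signal value only ranked regions within its own list. No read counts entered, so the depth behind each region is unknown. A control experiment was not used here. Coordinates are those of the ce11 build unless another build is named.

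The strongest regions recurred in both replicates. Replicate 1 listed 26700 regions and replicate 2 listed 24791. Of the 100 strongest regions of replicate 1, 69 had 1 of the 100 strongest regions of replicate 2 with its summit within 200 bp, where a random ranking of replicate 2 shared 0.435% on average. For the 319 strongest regions, the number of peaks called, 186 were shared (58.3%, against 1.32% on average and 3.76% at most in 1000 random re-rankings, one-sided permutation p = 0.001, the smallest that 1000 re-rankings can give). The shared part fell with the length of the list, to 45.6% of 1000 regions and 28.4% of 5000, where random rankings shared 10.7%. Both replicate lists were made with the same further file, and the random re-rankings make no allowance for what it may add to the overlap. Among the 319 called peaks, 182 lay among the 319 strongest regions of both replicates and 33 among those of neither. Both replicates ranked 276 of the called peaks within their 1000 strongest regions. The called list was derived from these same replicate lists by recurring ranks, so high ranks of called peaks in both follow from how it was made.

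**Figure D1:**
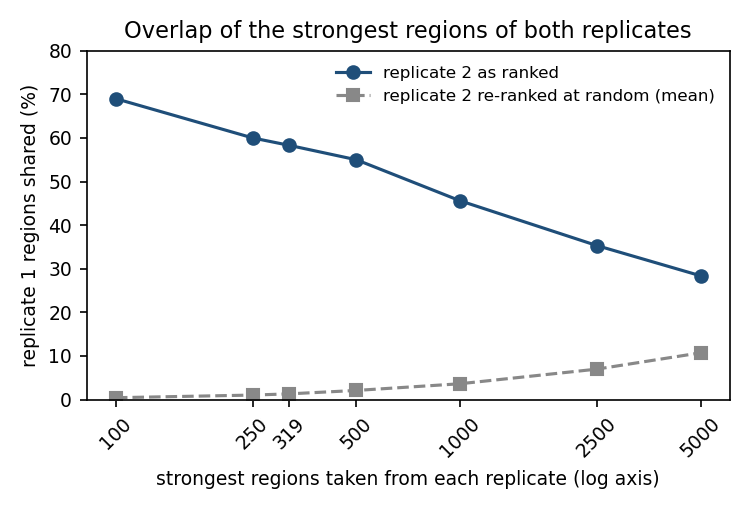
The share of the strongest regions of replicate 1 (vertical axis, %) that were also among the strongest of replicate 2, by the number of regions taken from each replicate (horizontal axis, log scale), with circles for the real ranking and squares for the mean of 1000 random re-rankings. The real share falls from 69% of 100 regions to 28.4% of 5000 and lies above the random mean at each of the 7 sizes.

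Called peaks lay at the 5′ ends of protein-coding genes more often than uncalled regions, though most of the 25 strongest nuclear peaks did not. The strongest nuclear peak (chromosome III, 3867491 to 3867631, signal value 248) lay 269 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit. It was followed by a peak 1190 bp upstream of nhr-76 itself (chromosome IV, 626162 to 626531, signal value 240), a peak 170 bp upstream of cdc-48.1, an AAA ATPase that unfolds ubiquitinated proteins (chromosome II, 10563484 to 10563656, signal value 232), and a peak between the divergent genes rpl-15 and K11H12.8 (chromosome IV, 654743 to 655112, signal value 228). Other promoters among the 25 strongest nuclear peaks were those of rpl-20 and Y17G9B.5 (signal value 191), F21C10.10 (171), rpl-35 (153), the histone gene his-37 (152), nhl-2 with tag-340 (140), and tasp-1 with K01G5.10 (138). Each of these was among the 50 strongest regions of both replicates, except the peaks at nhl-2 and tasp-1, which ranked 38 and 43 in replicate 1 and 117 and 87 in replicate 2. The rest of the 25 strongest nuclear peaks, the one upstream of nhr-76 among them, had their summit outside the promoter window. The choice of nuclear peaks was made after the data were seen, because 25 of the 31 strongest called peaks were mitochondrial.

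Across all 319 called peaks, 179 summits (56.1%) lay in a promoter window, from 1000 bp upstream to 200 bp downstream of a protein-coding gene's 5′ end, against 29.7% of the 12728 pooled regions that were not called (odds ratio 3.03, 95% interval 2.42 to 3.78, two-sided Fisher's exact test, adjusted p = 2.2e-21 over 4 classes). Introns held 14.4% of called and 33.05% of uncalled summits (odds ratio 0.344, exact adjusted p = 2.1e-13), and exons 7.84% and 13.1% (odds ratio 0.572, adjusted p = 0.0054). The intergenic share was 21.6% against 24.1% and did not pass the test (odds ratio 0.873, exact adjusted p = 0.32). The exon difference was lost with a promoter window of 500 bp (odds ratio 0.750, exact adjusted p = 0.143) and among the 159 strongest called peaks (odds ratio 0.609, adjusted p = 0.0997). In the nucleus, the 200 pairs of gene and summit in this window had the summit at a median of -255.5 bp from the gene's 5′ end (quartiles -454 and -162 bp), in a window that itself reaches further upstream than downstream. Peaks are not biological replicates, so these tests describe this set of regions. The uncalled regions came from a list of peaks and background, and they were not matched to the peaks on GC content or repeats. Mean GC of the 200 bp windows was 40.2% at called peaks and 33.1% at all uncalled regions. Sequence masked as repeats held 17.4% of nuclear called and 46.0% of uncalled nuclear summits. How far the location differences follow from these was not tested. Against the stronger uncalled regions only, the promoter odds ratio was 2.49.

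**Figure D2:**
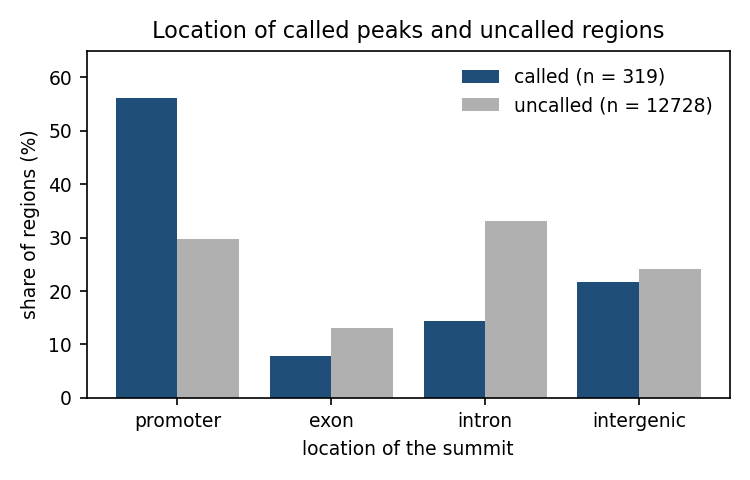
Share of summits (vertical axis, %) in each location class for the 319 called peaks (dark bars) and the 12728 uncalled pooled regions (grey bars). Promoters hold 56.1% of called and 29.7% of uncalled summits, and introns 14.4% and 33.05%.

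Ribosomal protein genes stood out among the genes with a called promoter. Of 4254 genes with any pooled region in the promoter window, 210 had a called summit there, 198 of them nuclear. For the ribosomal proteins this was 13 of 49 genes (odds ratio 7.51, 95% interval 3.96 to 14.2, two-sided Fisher's exact test, adjusted p = 7.7e-06 over 20 lists). Besides rpl-3, rpl-15, rpl-20 and rpl-35, they were rpl-12, rpl-24.2, rps-1, rps-12, rps-15, rps-19, rps-20, rps-23 and rps-26, of which those beyond the 4 strongest were named after their values were seen. No other list passed the threshold. Background genes were not matched on signal or GC content, and their pooled regions may be background signal rather than peaks. Whether the ribosomal promoters would also be recovered without the tagged protein was not tested. The odds ratio for ribosomal proteins lay at 12.4 and 9.36 when replicate 1 or replicate 2 was left out. With only the nearest gene, 6 of 29 had a called promoter (odds ratio 6.01, exact adjusted p = 0.031). In that setting a summit in several promoter windows counted only for the closest gene, which for some was a neighbour of the ribosomal gene.

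Stress response genes had 4 called promoters among 16 (odds ratio 7.03, exact adjusted p = 0.066). They were hsp-1 (signal value 125), hsp-110 (86.3) and hsp-60 (75.9), which encode chaperones, and daf-16 (76.2), the forkhead factor of insulin signalling. This list passed without replicate 2 (odds ratio 9.53, exact adjusted p = 0.0073) and with a 2000 bp window (odds ratio 7.21, adjusted p = 0.0134) or all genes as the background (odds ratio 12.8, adjusted p = 0.0040). It did not pass with a 500 bp window (odds ratio 6.45, exact adjusted p = 0.24), among the 159 strongest called peaks (7.24, adjusted p = 0.50), with only the nearest gene (4.62, adjusted p = 0.57) or without replicate 1 (7.10, adjusted p = 0.064). Nuclear receptor genes had 8 of 70 (odds ratio 2.67, exact adjusted p = 0.10), led by nhr-79 (signal value 74.9), nhr-68 (72.6), nhr-48 (69.5) and nhr-58 (68.2). This list passed with all protein-coding genes as the background (odds ratio 3.07, exact adjusted p = 0.043) and with a 2000 bp window (11 of 99, odds ratio 2.66, adjusted p = 0.028). Among the 159 strongest called peaks the odds ratio was 0.288, and without replicate 1 or replicate 2 it was 1.004 and 1.32. Chemoreceptor genes, a large family expressed mainly in sensory neurons, had 1 called promoter among 127, that of srh-16 (odds ratio 0.222, exact adjusted p = 0.10). That list passed with a 2000 bp window (odds ratio 0.150, exact adjusted p = 0.0134) and with all genes as the background (odds ratio 0.102, adjusted p = 0.00017). Without replicate 2 it had 2 of 128 (odds ratio 0.377, exact adjusted p = 0.61), and it did not pass with a 500 bp window (odds ratio 0.314, adjusted p = 0.65) or with only the nearest gene (0.271, adjusted p = 0.42).

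Genes of fat metabolism did not pass the test under any of the settings tried. The list had 1 called promoter among 23 genes, that of pmt-1, a methyltransferase of phosphatidylcholine synthesis (chromosome II, 5282863 to 5283232, signal value 65.8, odds ratio 1.28, 95% interval 0.244 to 6.72, exact adjusted p = 1.00). So few called genes leave the value loose, with 0 of 23 without replicate 1 (odds ratio 0.410), 3 of 30 with a 2000 bp window (2.56) and 2.59 with all genes as the background. The promoter window of atgl-1 (chromosome III, 6415772 to 6419459, minus strand) held no called summit. It held 2 pooled regions, the stronger at rank 3802, and the nearest called summit lay 1812 bp from the gene's 5′ end. The window of npr-22, a neuropeptide receptor gene of the same fat-loss pathway, held no region in the pooled list or in either replicate, and the nearest called summit lay 24279 bp away. With a 2000 bp window, 2 of 4 background genes of the serotonin and FLP-7 fat-loss pathway had a called summit (odds ratio 20.1, exact adjusted p = 0.042), where the 1000 bp window gave 0 of 3. The summits 1190 bp upstream of nhr-76 and 1812 bp upstream of atgl-1 came into that wider window, and the region of nhr-76 held more listed regions than chance in this strain, as given with the locus. With that window, core histones also passed (odds ratio 15.7, adjusted p = 0.0161, against 1 of 6 genes, exact adjusted p = 0.75, with 1000 bp).

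Of the mitochondrial respiratory chain genes in the nucleus, 2 of 20 had a called promoter, cox-5A (signal value 138) and atp-1 (65.3), and of the cuticle collagens 1 of 43 did, col-119 (64.3). No promoter was called among 38 immune effectors, 28 cytochrome P450 and UGT enzymes or 15 homeobox and other developmental regulators. The lists of tissue markers had few genes in the background and no called promoter among them, with 3 intestine, 2 hypodermis, 6 body wall muscle, 3 pharynx, 2 neuron and 3 germline genes, nor did 3 molting genes and 1 vitellogenin gene. None of these lists passed the test, and the exact adjusted p was 0.749 or higher for each.

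**Figure D3:**
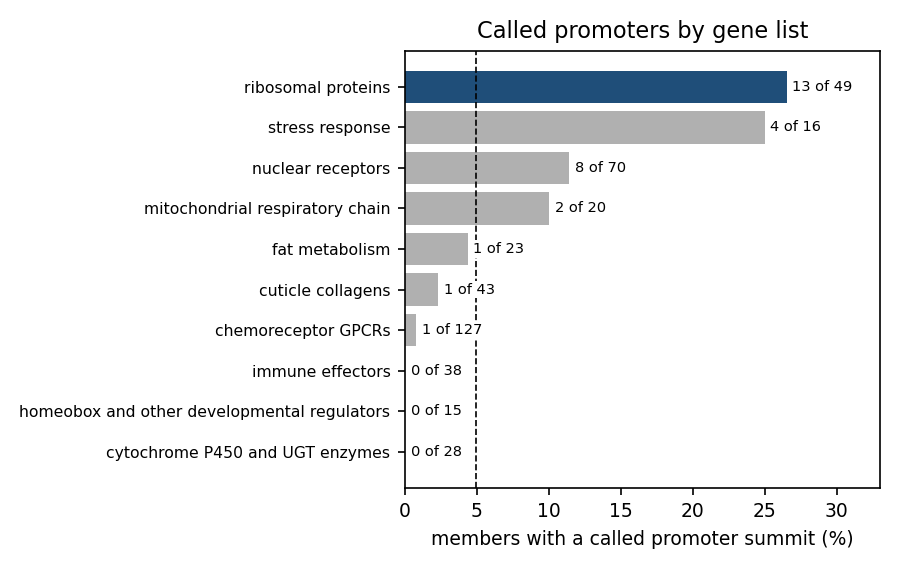
Share of list members with a called summit in the promoter window (horizontal axis, %), for the 10 lists with at least 10 genes in the background, with the counts beside each bar and the dashed line at 4.94%, the share of all background genes. Ribosomal proteins (dark bar, 13 of 49) are the only list that passed the test, and stress response (4 of 16) did not pass.

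By signal value, mitochondrial DNA led the called peaks. It held 31 of the 319 called peaks (9.72%) and 3 of the 12728 uncalled regions (odds ratio 397, 95% interval 131 to 1205, two-sided Fisher's exact test, adjusted p = 9.8e-47 over 7 chromosomes). Their median signal value was 502, against 74.8 for the 288 nuclear peaks, and the highest, 4339, lay at positions 4542 to 4963 of the mitochondrial chromosome, inside another gene and upstream (-929 bp) of COX3, which encodes a subunit of cytochrome c oxidase. The pooled list held 30 mitochondrial regions, and an uncalled one had to lie over 200 bp from every called summit. With called peaks along most of the molecule, few could remain uncalled, so this definition largely set the odds ratio of 397 and its p. The 31 peaks covered 8446 of the 13794 bp of mitochondrial DNA (61.2%). Left out, they changed no test of location or gene lists, while the calls for small RNA genes and for runs of T were lost, as given with those results.

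On the autosomes, called peaks favoured the centre of each chromosome, the gene-dense part in this species. The centre, set before the data were examined as 1 of 3 equal parts, held 52.6% of called and 36.2% of uncalled autosomal summits (odds ratio 1.961, 95% interval 1.51 to 2.55, Fisher's exact test, p = 6.4e-07). No single chromosome's centre was tested. The comparison was not matched on repeats, and sequence masked as repeats held 18.9% of autosomal called and 46.0% of uncalled nuclear summits. Chromosome IV held 13.5% of called and 18.8% of uncalled summits (odds ratio 0.680, exact adjusted p = 0.056), and this passed without replicate 1 (odds ratio 0.643, adjusted p = 0.0199) and without the 50 kb around nhr-76 (odds ratio 0.640, adjusted p = 0.0227), but not without replicate 2 (odds ratio 0.755, exact adjusted p = 0.12) or without mitochondrial peaks (odds ratio 0.766, adjusted p = 0.61).

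The X chromosome held 60 of the 288 nuclear peaks (20.8%) and 17.9% of the uncalled nuclear regions, which did not differ by the test (odds ratio 1.22, Fisher's exact p = 0.21). Among the 159 strongest called peaks it did (odds ratio 1.88, exact p = 0.0024), and also without replicate 1 (odds ratio 1.37, p = 0.036), but not without replicate 2 (odds ratio 1.25, p = 0.14). Of the 50 strongest nuclear peaks, 20 were X-linked. Called X peaks lay away from genes more often than called autosomal ones. In promoters lay 18 of 60 X peaks and 136 of 228 autosomal ones (odds ratio 0.295, 95% interval 0.161 to 0.541, Fisher's exact test, adjusted p = 0.00027), and their intergenic share was 41.7% against 18.9% (odds ratio 3.06, adjusted p = 0.0010). Uncalled regions showed a smaller gap, with 33.5% intergenic on X and 22.1% on autosomes. The strongest X peaks lay at 2996941 to 2997310 in an intron of Y41G9A.17 (signal value 194), at 1389367 to 1389736 (176), at 11094008 to 11094377 (176) and at 16681942 to 16682311 (173), the last 3 of them intergenic.

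**Figure D4:**
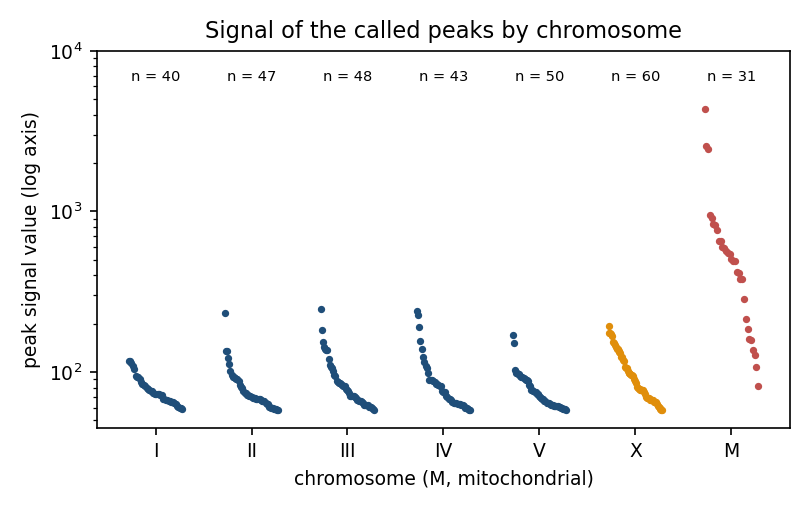
Signal value (vertical axis, log scale) of each of the 319 called peaks, 1 point per peak in falling order, by chromosome (horizontal axis; M, mitochondrial). Mitochondrial peaks reach 4339, while no nuclear peak exceeds 248.

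Of the sequences under called summits, an E-box and a GAGA repeat passed the test as more frequent, and the 4 nuclear receptor elements tested did not pass against the matched background. Windows of 200 bp at called summits were compared with 5 uncalled regions per peak, matched on promoter class and GC content (mean GC 40.2% against 40.0%). The element AGGTCA occurred in 6.27% of called and 5.89% of matched windows (odds ratio 1.09, 95% interval 0.664 to 1.78, Fisher's exact test, adjusted p = 0.80 over 19 motifs), the longer AAGGTCA in 3.45% and 2.01% (odds ratio 1.79, 95% interval 0.905 to 3.55, adjusted p = 0.34), and the variant AAGTCA in 10.3% and 6.83% (odds ratio 1.59, 95% interval 1.06 to 2.38, adjusted p = 0.11). The DAF-12-type element AGTGCA leaned the other way, with 6.58% and 8.78% (odds ratio 0.746, 95% interval 0.466 to 1.19, exact adjusted p = 0.43). AAGGTCA passed against the unmatched background (odds ratio 2.43, 95% interval 1.32 to 4.45, exact adjusted p = 0.048), and its odds ratio was 2.27 without replicate 2, 2.05 without the nhr-76 neighbourhood and 2.4997 without mitochondrial peaks (95% interval 1.22 to 5.12, exact adjusted p = 0.12). It was lower, at 1.75, without replicate 1 and 1.40 among the 159 strongest called peaks (95% interval 0.423 to 4.64). In 100 bp windows the odds ratio of AAGGTCA was 3.02 (95% interval 0.933 to 9.78). A moderate excess of AAGGTCA is therefore not ruled out. The main comparison set 31 mitochondrial windows against an almost wholly nuclear background. Without mitochondrial peaks, the odds ratio of AGGTCA was 1.31 (95% interval 0.791 to 2.16, Fisher's exact test, adjusted p = 0.48). The E-box CACGTG, bound by basic helix-loop-helix factors, was found in 14.4% against 6.52% (odds ratio 2.43, 95% interval 1.68 to 3.51, exact adjusted p = 0.00018), and the GAGA repeat GAGAGAG in 19.4% against 10.5% (odds ratio 2.07, 95% interval 1.504 to 2.85, adjusted p = 0.00018). Against the unmatched background the odds ratios were 4.27 for the E-box and 4.12 for the GAGA repeat, so their size depended on the matching. Runs of T (TTTTTTTT) were found in 15.05% against 21.9% (odds ratio 0.635, exact adjusted p = 0.032), a call that was lost under most alternatives, among them without replicate 1 (odds ratio 0.903), replicate 2 (0.792), the mitochondrial peaks (0.876) or the nhr-76 neighbourhood (0.677), and kept against the unmatched background (0.347). Among the 159 strongest called peaks none of the 19 motifs passed, with odds ratios of 2.06 for the E-box (exact adjusted p = 0.214) and 1.26 for the GAGA repeat (adjusted p = 0.69). Of all 2080 6-mers, 37 were more and 32 less frequent at called summits, and among the more frequent ones AGAGAA (45.5% against 29.2%), GAGAGA (39.8% against 24.8%), ACGCAG (23.2% against 12.2%) and CGTCTC (27.3% against 15.5%) were the most significant, with adjusted p from 5.6e-05 to 0.00052. Without replicate 1, the counts were 17 more and 7 less frequent, without replicate 2 they were 41 and 22, and among the 159 strongest called peaks 1 and 0.

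Genes of small RNAs were near 21 of the called summits. Within 200 bp of a tRNA, snRNA, snoRNA or rRNA gene lay 6.58% of called and 2.15% of uncalled summits (odds ratio 3.27, 95% interval 2.08 to 5.14, Fisher's exact test, p = 1.2e-05). Without the mitochondrial peaks, 9 remained and the difference was lost (odds ratio 1.55, exact p = 0.30). In the nucleus they included sls-2.1, sls-2.4 and sls-2.2, genes of the SL2 spliced leader RNA (signal values 123, 108 and 76.3), which were named after their values were seen.

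At the nhr-76 gene (chromosome IV, 627537 to 633963, plus strand), 3 called summits lay within 50 kb, against 0.259 on average at 10000 random positions of the chromosome (one-sided permutation p = 0.0091), and 3 of the strongest 1% of pooled regions did, against 0.101 (p = 0.0038). The called peaks were the one 1190 bp upstream of the gene, one in its intron (629197 to 629566, signal value 89.5, rank 80 in replicate 1 and 205 in replicate 2) and the one at rpl-15. The strain carries a transgene of nhr-76, so reads at this locus can come from the transgene as well as from the gene's own copy. Uncalled pooled regions were also dense there, with 19 within 20 kb against 6.35 at random positions (permutation p = 0.0015), but less so within 50 kb (25 against 14.5, p = 0.033) and not within 100 kb (30 against 28.1, p = 0.41). Within 50 kb, the regions of replicate 1 (38 against 29.6, permutation p = 0.14) and replicate 2 (39 against 28.01, p = 0.072) did not pass.

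**Figure D5:**
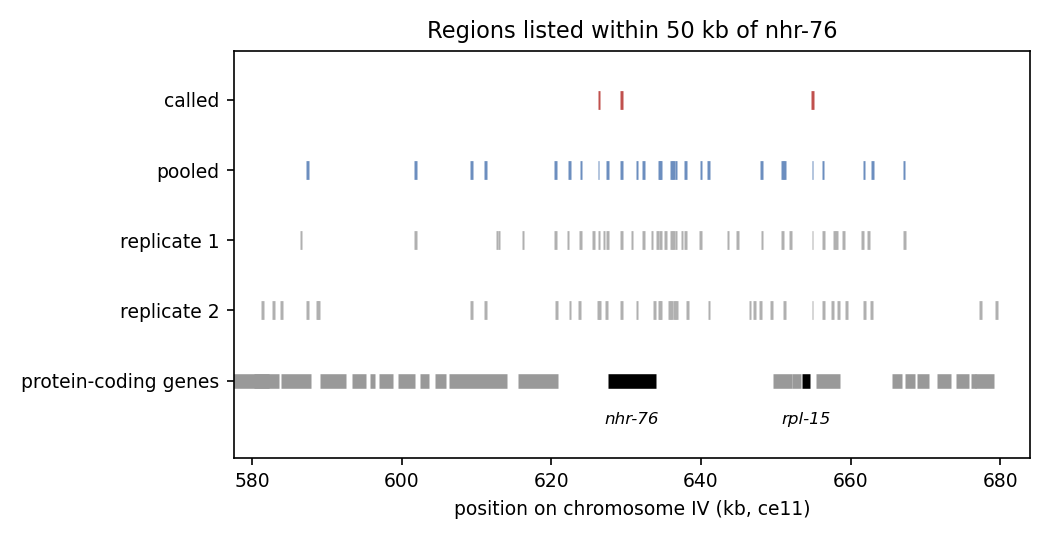
Regions listed within 50 kb of nhr-76 on chromosome IV (horizontal axis, position in kb, ce11), in rows for the called peaks, the pooled list, each replicate and the protein-coding genes, drawn to scale. The 3 called peaks lie upstream of nhr-76, within it and at rpl-15, and the pooled regions crowd within 20 kb of nhr-76.

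The lists of the older build gave nearly as many peaks. There were 316 called peaks in ce10 and 319 in ce11, and 299 and 310 when overlapping peaks were merged. Chromosome by chromosome, the ce10 and ce11 lists held 40 and 40 on I, 45 and 47 on II, 46 and 48 on III, 39 and 43 on IV, 52 and 50 on V, 61 and 60 on X, and 33 and 31 on mitochondrial DNA. These counts are values with no test.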

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

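Leaving out the mitochondrial peaks, alone or with the X-linked ones, was chosen after seeing the data. Of 185 alternative values for 27 results, 148 kept their direction and their side of the threshold, or for counts stayed within 1.5 times. These include all alternatives for promoter, intron and intergenic location, mitochondrial and X-linked peaks against all others, the centre of autosomes, ribosomal proteins (odds ratios 6.01 to 19.96), the nhr-76 locus and replicate overlap (53.9 to 59.2%). The cause was not tested for any value that changed.

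With the 159 strongest called peaks, fewer by construction, calls ended for exons (0.609), the E-box (2.06), the GAGA repeat (1.26) and runs of T (0.595), 0 motifs and 1 6-mer passed, X against autosomes passed (1.88), and the odds ratio of nuclear receptors turned to 0.288, on no call. A 500 bp promoter window ended the exon call (0.750). With 2000 bp, 6 lists passed instead of 1, among them nuclear receptors (2.66), stress response (7.21), chemoreceptors (0.150), the serotonin and FLP-7 pathway (20.1) and core histones (15.7). With all protein-coding genes as background 4 lists passed, with nuclear receptors at 3.07, stress response at 12.8 and chemoreceptors at 0.102. Chromosome IV passed without the nhr-76 neighbourhood (0.640).

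Without replicate 1 or 2, the values were 0.643 and 0.755 for chromosome IV, 1.37 and 1.25 for X against autosomes, 1 and 2 lists passed, 7.10 and 9.53 for stress response, 5 and 3 motifs passed (the SL1 acceptor TTTTCAG in both, at 0.549 and 0.530, and the tRNA B box and PHA-4 site without replicate 1), 24 and 63 6-mers passed, and 0.903 and 0.792 for runs of T, whose call both ended. Runs of T were also lost without the nhr-76 neighbourhood (0.677), without mitochondrial peaks (0.876), also without X-linked ones (0.789), and in 100 bp windows (0.580). Against 69 6-mers in the main comparison, 40 passed without X-linked and mitochondrial peaks, 36 in 100 bp windows and 555 against the unmatched background, where 7 motifs passed instead of 3, the nuclear receptor element AAGGTCA (2.43) among them. Small RNA genes lost their call without mitochondrial peaks (1.55). No paired analysis was possible because the design has 1 group. Depth is unknown, so how far it limits the weaker regions was not tested.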

Other observations

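The gene lists, elements and comparisons in these observations were chosen after the results were seen, apart from 2 tests set before their results were seen (the surroundings of other strong peaks and the GC content of X-linked peaks).

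Beyond the ribosomal proteins, genes of 2 further groups, translation factors and subunits of the chaperonin, prefoldin and proteasome, had called promoters. Among 22 translation factor genes in the background, 5 did (eef-1A.1, eef-1A.2, eef-1G, eif-3.C and iff-2), with an odds ratio of 6.16 (95% interval 2.34 to 16.22, Fisher's exact test, adjusted p = 0.0074 over 2 lists). Of 20 genes for subunits of the chaperonin, prefoldin and proteasome, 4 did (cct-1, cct-8, pfd-1 and rpn-3), with an odds ratio of 5.32 (95% interval 1.86 to 15.2, exact adjusted p = 0.015). Both gene families were chosen after the bound genes had been read, so these p-values are not independent evidence and overstate it.

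On the autosomes, the 8-mer GACGCAGA was found at 43 of 228 called summits (18.9%) and at 6.93% of matched uncalled regions (odds ratio 3.13, 95% interval 2.10 to 4.68, Fisher's exact test, adjusted p = 0.0047 over all 8-mers), and the longer GAGACGCAGA at 15.4% against 5.53%. Called promoters with the 8-mer included those of set-16 and drr-2, sec-61.G, the glycosyltransferase gene ogt-1, cdk-7 and efl-1. Of its matches at called summits, 64.4% lay in sequence masked as repeats, as did 51.9% of those at matched regions, while 18.9% of autosomal called and 46.0% of uncalled nuclear summits were masked.

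The first pattern is the 31 mitochondrial peaks. Reads from the many copies of mitochondrial DNA in each cell may have been called along the whole molecule, of which the peaks covered 61.2%. Whether the tagged protein bound there stays open. The mitochondrial chromosome holds 0 copies of CGTCTC, a 6-mer of 87 of 288 nuclear windows, so the outcome of its test was fixed (0 of 31, odds ratio 0.0366) and decides nothing about binding. The design has 1 group, so for none of the 3 patterns was a biological explanation tested by comparing groups.

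The second pattern is the crowding of uncalled regions around nhr-76. Spread of signal around any strong peak was examined at the 50 strongest other nuclear peaks. Of these, 0% had as many as 19 uncalled regions in a window of the size used at nhr-76, with a median of 7 and a highest count of 18. The count at nhr-76 was thus above that of the median strong peak, but the margin over the highest was narrow. The nhr-76 window held 2 called peaks, which the comparison did not match, so spread is not ruled out. Extra copies of the cloned region in the tagged strain are another candidate explanation. The excess was local (19 against 6.35 within 20 kb, permutation p = 0.0015). It was also found in replicate 1 (28 against 12.9, permutation p = 0.0070) and replicate 2 (24 against 12.2, p = 0.0138) at that distance. The distance was fixed beforehand for called peaks and applied to these regions after their counts were seen. These counts restate the pattern, so they cannot tell extra copies from another cause of a local excess. How many copies the strain carries, and whether the 3 called peaks there reflect binding, was not tested.

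The third pattern is the share of X-linked peaks among the strongest nuclear ones, 20 of 50 against 17.9% of uncalled regions (odds ratio 3.09). Matching on GC content lowered this odds ratio but did not remove it. Against uncalled regions of the same GC decile it was 2.35 (95% interval 1.32 to 4.20, Fisher's exact p = 0.0056), with the low end near the bound of 1.2 set for this test. The cut at 50 peaks was not among the alternatives fixed beforehand, and across all 288 nuclear peaks X did not differ (odds ratio 1.22, exact p = 0.21). The interval and p make no allowance for that choice, so the test does not settle whether GC content is the whole cause. A candidate explanation is that these peaks lie at sites where the dosage compensation complex, which lowers X-linked transcription in hermaphrodites, is recruited to X. The recruitment element TCGCGCAGGGAG, tested because 8-mers like it had been seen at these peaks, with at most 2 mismatches, was in 14 of 60 X-linked called windows and 4 of 300 matched X-linked uncalled ones (odds ratio 20.5), and 1 of 200 shuffled elements gave as large a value. These counts restate the 8-mers and are not independent evidence, and whether the sites would also be recovered without the tagged protein, as highly accessible chromatin might be, was not tested.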
